A study of Mus musculus with 67 samples.

How the data were processed

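Gene expression was measured on 67 two-colour Agilent whole mouse genome arrays, each comparing RNA of a mouse lung epithelial cell line with a common reference. Per the labels, the sample RNA carried Cy5 and a commercial pool of mouse reference RNA carried Cy3 on every array, with no dye swap among them. Per the series' design text, the authors applied LOWESS within arrays and tested genes with the R library MAANOVA. The scanner settings, background correction and spot filters were not given in the sources used here. The deposited value table holds 41174 probes with no missing value, and its values are used here as log2 ratios of sample over reference.

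The table states neither the log base nor the direction of the ratio. The values ran from -7.19 to 7.02, which on a log10 scale would exceed what a scanner of that kind can record, so log10 was ruled out; a natural log stays open, in which case every difference below would be in natural log units. The direction was taken from the dyes, sample over reference. Every pair of arrays correlated positively over all probes, from 0.57 to 0.97, so all arrays run the same way, but an inversion of all of them would turn each rise into a fall. Array medians ran from -0.0087 to 0.019 and array SDs from 0.49 to 0.68. The values carry no brightness or background, so no dim probe was left out, and the small number of arrays per group limits the precision.

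Groups were taken from the labels: 2 condensates, each with a control and 3 doses, harvested after 6 h of exposure or after a further 4 h of recovery. Arrays are named here by the submitters' sample numbers. Array 35, a 6 h control, is said in the labels to serve both condensates and entered both fits. It was left out of the cannabis side wherever the condensates were set against each other. No number is shared between groups, so the labels give no pairing, and no processing batch is stated. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The highest correlation between any 2 arrays was 0.972, and none held identical values.

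The values were fitted per probe with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), without further normalisation. The tobacco fit held 35 arrays and 27 residual degrees of freedom, and the cannabis fit 33 arrays and 25. A joint fit of all 67 arrays, with 51 residual degrees of freedom, tested differences between the condensates. A probe was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The comparisons against control, the tests of differences between times and between condensates, the correlations and nearly all alternatives were fixed before the data were examined. The comparisons of the highest with the lowest dose, of the controls with each other, the sets of probes followed across arrays, and the alternatives without 3 arrays and with runs of sample numbers as a block were added afterwards. A run held 8 consecutive numbers of one condensate, the last tobacco run 25 to 35, and array 35 joined the first cannabis run in the cannabis fit. Each run mixed several groups, and controls of different condensates cannot be compared within runs. The mean of a set of probes was compared between exposed and control arrays by exact two-sided permutation tests, 72 in all, with Benjamini-Hochberg adjustment over the 72.

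No table pairing these probes with genes was used here, so 0 probes carry a gene name. The rule fixed in advance for naming genes took the largest rises and falls at each highest dose among called genes whose exposed arrays all lay beyond every control. It yields no gene here, nor could the 17 pathway lists and 5 cell type marker lists fixed in advance be tested. The design planned gene averages, and the fit was made per probe instead, so a gene with several probes counts several times. In place of genes, 4 probes are followed by identifier. They are those with the largest rise and the largest fall at the highest dose after 6 h in each condensate among called probes with fully separated groups, a choice of order made after the values were seen.

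The fit was tested on simulated data made from the real probes and whole-array residuals reassigned at random, with 200 of 41174 probes changed. For the highest tobacco dose at 6 h, 85% of changes of 1 log2 unit and 99% of changes of 2 were recovered, with 0 false calls. After recovery these were 83% and 99%, with 5 false calls. For the highest cannabis dose they were 93% and 99% at 6 h, with 98 false calls, and 85% and 98% after recovery, with 8. Residuals of whole arrays move many probes together, so false calls come in clusters. The 98 false calls, beside 200 planted changes, exceed what the adjusted threshold gives on average, and the real count of that comparison may hold such a cluster. Only 1 draw was made per comparison, and changes under 1 log2 unit, the size of most called ones at the highest doses, were not simulated. The alternatives tried were centring each array on its median, quantile normalisation, leaving out the 25% of probes with the lowest mean, no moderation of the spread, array weights, a fit of only the groups compared, an added requirement of a 1.5-fold change, pooled controls, the shared control moved to the cannabis side, and each array left out in turn. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.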

Results

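The study compared how smoke condensates of tobacco and of marijuana act on mouse lung epithelial cells. The cells were a line of pulmonary epithelium from the Muta Mouse, a transgenic strain made for scoring mutations. Condensates are the particulate matter of mainstream smoke, collected on a filter and dissolved in dimethyl sulfoxide. Cells received tobacco condensate at 0, 25, 50 or 90 µg/ml or marijuana condensate, called cannabis in the labels, at 0, 2.5, 5 or 10 µg/ml. The labels do not say whether the controls at 0 µg/ml received dimethyl sulfoxide, so an effect of the solvent is not excluded. They were harvested after 6 h, or washed and kept for another 4 h in fresh medium. The 16 groups held 67 arrays. Tobacco groups at 6 h had 6 control arrays and 4, 5 and 4 arrays by rising dose, and after recovery 3 control arrays and 4, 4 and 5. Each cannabis group had 4 arrays, and the 6 h comparisons also used array 35, a control shared with tobacco. Values are log2 ratios to a reference RNA, on the assumed base and direction, and each of 41174 probes was tested. If the ratio ran the other way, every rise given here would be a fall and every fall a rise, with the same sizes, counts and tests. Counts are of probes, which are not paired with gene names here.

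The first question was what tobacco condensate changed at the end of the exposure. With rising dose, 51, 444 and 1074 probes rose and 12, 296 and 807 fell, so that 81%, 60% and 57.1% of the called probes rose. Among the probes called at 90 µg/ml the median change was 0.68, and 378 changed by more than 1 log2 unit, with extremes of 3.62 and -1.95. Probe A_51_P514961 had most of its rise at the lowest dose. It lay at -1.69 ± 0.47 (SD, n = 6) in controls and at 1.03 ± 0.26 (n = 4), 1.18 ± 0.49 (n = 5) and 1.93 ± 0.54 (n = 4) by rising dose. Its rise at 90 µg/ml was 3.62 ± 0.25 (SE; limma, Benjamini-Hochberg adjusted p = 1.81e-10), while its difference of 0.89 between 90 and 25 µg/ml did not pass (limma adjusted p = 0.125, but 0.0491 without array 1 and 0.0224 with runs of 8 consecutive sample numbers as a block). Probe A_52_P244682 fell in steps, with differences of -0.37, -1.02 and -1.95 from controls at 1.70 ± 0.35 (n = 6). The first of these did not pass in limma (adjusted p = 0.952) and the others did (adjusted p = 0.00107 and 8.81e-08).

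By limma with Benjamini-Hochberg adjustment the totals were 63, 740 and 1881 probes. Of the 1881, 1277 had exposed arrays all beyond every control, a separation that 4.66% of all probes showed and that chance gives in 0.95%. Between 90 and 25 µg/ml, 362 probes were higher and 196 lower at the higher dose. Single arrays moved the smaller counts: 25 µg/ml gave 41 probes without array 12, 41 without control 23 and 34 without array 30, and 50 µg/ml gave 453 without array 18 and 466 without array 31. When only the groups compared were fitted, 25 and 90 µg/ml gave 10 and 1010 probes and the difference between the doses 33. That difference came to 370, 253, 339 and 294 probes without arrays 7, 33, 17 and 30.

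**Figure D1:**
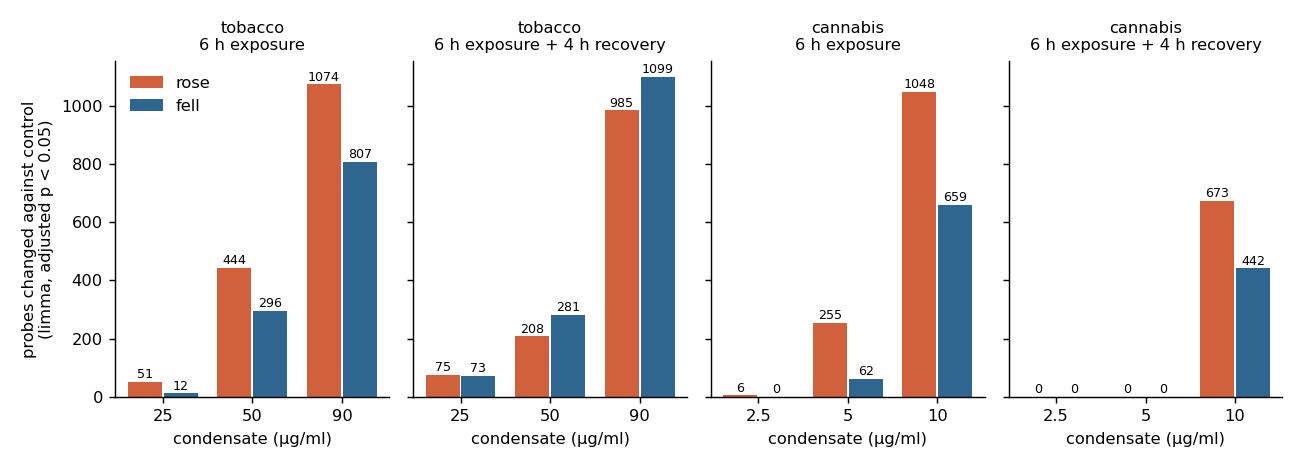
Number of probes that rose (orange) or fell (blue) against the control of the same condensate and time, by condensate concentration in µg/ml, at a limma adjusted p under 0.05. Counts grew with dose in the tobacco panels and in the cannabis 6 h panel, to 1074 and 1048 probes that rose at 6 h, and were 0 at the lower cannabis doses after recovery.

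After 4 h of recovery from tobacco the response was still present at each dose. By rising dose, 75, 208 and 985 probes rose and 73, 281 and 1099 fell against the recovery controls. The balance of rises and falls was not stable. With pooled controls 70, 201 and 1332 rose and 40, 148 and 1226 fell, and with array weights 234 rose and 359 fell at the lowest dose. The call at 90 µg/ml had a median size of 0.75, and 491 probes changed by more than 1 log2 unit. A_51_P514961 stayed 3.39, 3.48 and 3.75 above controls at -2.04 ± 0.33 (n = 3), with limma adjusted p = 1.6e-09 at the highest dose. A_52_P244682 was lower than its controls by a log2 difference of -0.91 at 90 µg/ml (limma adjusted p = 0.0101, 0.0617 without control 19 and 0.0585 when only the groups compared were fitted). The 1074 probes that had risen at 6 h, taken as a set, were on average higher than recovery controls by 0.17, 0.33 and 0.62 by rising dose. In exact two-sided permutation tests p was 0.0571, 0.0286 and 0.0179, adjusted over 72 tests to 0.0709, 0.042 and 0.042. The 807 that had fallen were lower, with differences of -0.18, -0.31 and -0.52 (exact permutation p = 0.0286, 0.0286 and 0.0179; adjusted p = 0.042 for each). These values of 0.0286 and 0.0179 are the smallest that the group sizes allow.

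The totals after recovery were 148, 489 and 2084 probes by limma with Benjamini-Hochberg adjustment, and 1888 of the 2084 had separated groups, against 11.2% of all probes and 3.57% by chance. Between 90 and 25 µg/ml, 327 probes were higher and 208 lower at the higher dose, 535 in all, 293 and 274 without arrays 4 and 15, 342 without the lowest 25% of probes, 1419 with array weights and 151 when only the groups compared were fitted. Fitted that way the doses gave 37, 185 and 798 probes. With only 3 recovery controls, each carried weight: without array 29 the totals were 41, 198 and 1096, without array 6 they were 82, 236 and 1318, and without array 19 they were 92, 260 and 1275. Without exposed arrays 15 and 26 the lowest dose gave 89 and 70 probes, without array 16 the middle dose gave 273, and without array 24 the highest gave 1242.

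Cannabis condensate at 6 h changed up to 1707 probes at concentrations several times lower by mass than those of tobacco. By rising dose, 6, 255 and 1048 probes rose and 0, 62 and 659 fell. At 10 µg/ml the median size of a called change was 0.73, and 429 probes changed by more than 1 log2 unit. Probe A_51_P432641 had the largest rise. It lay at -0.16 ± 0.13 (SD, n = 4) in the controls labelled cannabis and at 4.30 ± 0.93 (n = 4) at 10 µg/ml. Measured from the mean of -0.11 over the 5 controls of the fit, shared array 35 included, the rise was 4.41 ± 0.60 (SE; limma adjusted p = 4.47e-05). Its differences at 2.5 and 5 µg/ml were -0.12 and 2.42, neither of which passed (limma adjusted p = 0.991 and 0.0519, the latter 0.0366 without array 58, 0.0368 with quantile normalisation, 0.0114 with array weights, 0.0293 with runs of sample numbers as a block and 0.000341 with pooled controls). A_51_P514961 lay at -1.75 ± 0.33 in the controls labelled cannabis (-1.62 over the 5 of the fit) and at 0.89 ± 0.27, 1.40 ± 0.70 and 2.41 ± 0.76 by rising dose (SD, n = 4 each). Only the last passed in limma (adjusted p = 0.536, 0.0709 and 0.00227), with a spread shared by all cannabis groups, recovery included. In a fit of only the groups compared, its differences of 2.51 and 3.01 at the lower doses passed too (adjusted p = 0.0158 and 0.0141), as they did with pooled controls (0.0176 and 0.000185). The middle dose also passed with quantile normalisation (0.0453), array weights (0.00992) and runs as a block (0.0396). Probe A_51_P104012 had the largest fall, -2.06 ± 0.41 (SE; limma adjusted p = 0.00295), and A_52_P244682 fell by 1.90 (limma adjusted p = 0.000884).

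The totals were 6, 317 and 1707 probes by limma with Benjamini-Hochberg adjustment, and 1384 of the 1707 had separated groups, against 6.51% of all probes and 1.59% by chance. Between 10 and 2.5 µg/ml, 352 probes were higher and 220 lower at the higher dose, 572 in all, and 180 when only the groups compared were fitted. The doses fitted that way gave 18, 211 and 1060, and with runs of 8 consecutive sample numbers as a block they gave 14, 617 and 2853. The lowest dose gave 3 probes without array 63. The middle dose gave 189, 82 and 127 without arrays 36, 51 and 58, and 167 and 132 without controls 49 and 59. The highest gave 1105 and 1114 without arrays 47 and 52, and its difference from the lowest gave 319, 236, 322 and 301 without arrays 48, 52, 57 and 63.

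After recovery from cannabis, probes were called at the highest dose alone. At 10 µg/ml, 673 probes rose and 442 fell, with a median size of 0.80, and 314 changed by more than 1 log2 unit. A_51_P432641 remained 2.93 above its controls (limma adjusted p = 0.0138, and 0.0577, 0.0628, 0.0604 and 0.0508 without arrays 41, 55, 61 and 67). A_52_P244682 fell by 1.83 (limma adjusted p = 0.00918, and 0.0519 without array 61) and A_51_P104012 fell by 2.21 (limma adjusted p = 0.00952). A_51_P514961 was 2.40 above its controls and did not pass (limma adjusted p = 0.121, but 0.0187 without control 43, 0.00056 without arrays 43, 46 and 64 and 0.00011 with pooled controls). When only the groups compared were fitted, none of the first 3 passed. At 2.5 and 5 µg/ml limma called 0 probes, with 831 and 783 at an unadjusted p under 0.05, and 0 without moderation of the spread. Chance alone would give more than 831 at that threshold over 41174 probes. The 1048 probes that had risen at 6 h included 333 that also rose after recovery, where independent lists would share 17.1, though both lists come from the same fit.

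The arrays of these recovery groups did not hold together. A_51_P514961 ranged from -2.44 to 1.80 over the 4 arrays labelled control and from -2.54 to 1.60 over the 4 labelled 5 µg/ml. For a wider reading, 34 probes were taken for which all 26 exposed tobacco arrays lay beyond all 9 tobacco controls, 30 higher and 4 lower. In cannabis arrays the share of these on the exposed side was 0% to 5.88% in the 4 controls at 6 h. In the 12 exposed 6 h arrays it was 41.2% in array 57 at 2.5 µg/ml, below the 50% midpoint, and 61.8% to 91.2% in the others. After recovery it was 88.2%, 8.82%, 11.8% and 38.2% in the arrays labelled control (43, 55, 60 and 67) and 79.4%, 50%, 73.5% and 0% in those labelled 5 µg/ml (39, 44, 62 and 64). It was 38.2%, 8.82%, 88.2% and 85.3% in those labelled 2.5 µg/ml (42, 46, 54 and 65) and 88.2% to 94.1% at 10 µg/ml. The count at 10 µg/ml was 3011 without control 43, 112, 279 and 351 without controls 55, 60 and 67, and 281 and 131 without arrays 41 and 61. Leaving out arrays 43, 46 and 64, a choice made on the response itself after the data were seen, gave 0, 103 and 3388 probes by rising dose. The count at 10 µg/ml was 2 when only the groups compared were fitted. Between 10 and 2.5 µg/ml, 356 probes were higher and 228 lower, 584 in all. That count was 0 when only the groups compared were fitted and 2504 with array weights, and it was 1246 without array 65 and 99, 133, 337, 57, 74 and 16 without arrays 41, 42, 45, 46, 54 and 61.

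**Figure D2:**
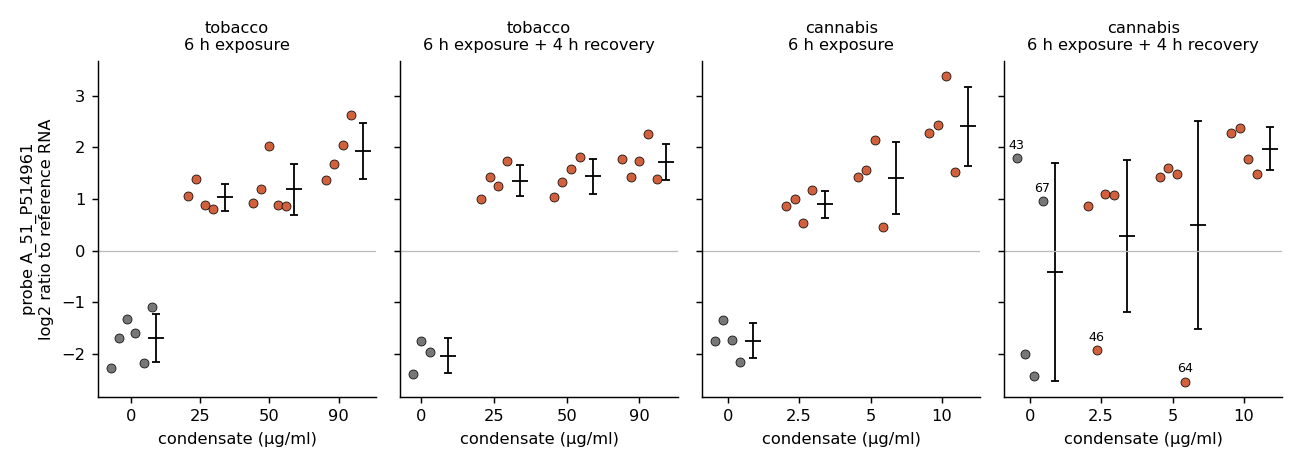
Log2 ratio of probe A_51_P514961 on each array (points; grey control, orange exposed) with the group mean and SD beside them, by condensate concentration in µg/ml. Control and exposed arrays were apart at both tobacco times and at 6 h of cannabis, while after cannabis recovery arrays 43 and 67, labelled control, lay above 0 and arrays 46 and 64, labelled 2.5 and 5 µg/ml, at -1.92 and -2.54.

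Few probes were called for a response that differed between the end of exposure and recovery. A test of this difference is less precise than one against controls. In tobacco the median SE over all probes was 0.154, against 0.102 at 90 µg/ml at 6 h and 0.116 after recovery. The fall of A_52_P244682 with tobacco differed by 1.04 ± 0.29 (SE) between times and was not called (limma adjusted p = 0.417). A low count therefore does not show that few responses differed. For tobacco at 90 µg/ml 19 probes differed, 10 higher after recovery and 9 lower, and 14 of them had the larger change after recovery. For cannabis at 10 µg/ml 15 probes differed, all with the larger change at 6 h, a count that 6 of 100 sets of random time labels reached, the real labels included. Their median change was 2.41 at 6 h and 0.24 after recovery, and 13 of the 15 were called at 6 h alone. Over all probes the changes at the highest dose correlated between times with r = 0.66 (Spearman 0.47) in tobacco and 0.70 (0.51) in cannabis, across probes, which are not independent replicates. In tobacco 467 probes rose and 329 fell at both times, where independent lists would share 25.7 and 21.5, and 4 of 800 called at both went opposite ways. In cannabis none of 511 did. The lists of a condensate come from the same fit with a shared spread, so they are not independent.

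By limma's test of the difference, 2265 tobacco and 1858 cannabis probes had an unadjusted p under 0.05 for a difference between times. These are about the numbers that chance gives at 0.05 over 41174 probes. The tobacco count was 12 and 6 without recovery controls 19 and 29, 33 without array 21 or 6 h control 23, and 10 without array 33. The cannabis count was 23 without control 43, 29 without array 56 and 34 without arrays 43, 46 and 64. When only the groups compared were fitted the counts were 1 and 0, and with runs of sample numbers as a block the tobacco count was 29.

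The main question of the design was how the condensates differ, asked here at the highest dose of each, 90 µg/ml of tobacco and 10 µg/ml of cannabis, which differ in mass. The lists shared more probes than independent lists would, though a minority of each. At 6 h 401 probes rose with both condensates, of 1074 with tobacco and 850 with cannabis, and 219 fell with both, of 807 and 642, where independent lists would share 22.2 and 12.6. Of the 622 probes called with both, 2 went opposite ways. After recovery 253 rose with both, of 985 and 682, and 179 fell, of 1099 and 454, against 16.3 and 12.1, and 2 of 434 went opposite ways. The changes correlated across probes with r = 0.65 (Spearman 0.46) at 6 h and 0.67 (0.50) after recovery, with no array in both comparisons. The overlap at 6 h was 405 without array 47. After recovery it was 974, 35, 112 and 128 without cannabis controls 43, 55, 60 and 67, 109, 273 and 43 without cannabis arrays 41, 45 and 61, and 277 without tobacco control 19. It was 831 with array weights and 1066 without arrays 43, 46 and 64.

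Sets called at 6 h with one condensate were followed in other arrays. The 1074 probes that rose with tobacco at 6 h were higher than controls by 0.20, 0.41 and 0.67 at 2.5, 5 and 10 µg/ml of cannabis at 6 h (exact two-sided permutation p = 0.0286 each, the smallest that 4 arrays against 4 allow; adjusted p = 0.042). The 807 that fell with tobacco had differences of -0.15, -0.31 and -0.54 (exact permutation p = 0.0571, 0.0286 and 0.0286; adjusted p = 0.0709, 0.042 and 0.042). The 850 probes that rose with cannabis at 6 h without the shared control were higher by 0.24, 0.43 and 0.63 at rising doses of tobacco (exact permutation p = 0.00476, 0.00216 and 0.00476; adjusted p = 0.0228 each). The 642 that fell had differences of -0.22, -0.33 and -0.46 (exact permutation p = 0.0381, 0.00433 and 0.00476; adjusted p = 0.0549, 0.0228 and 0.0228). In tobacco recovery arrays those 850 were higher by 0.12, 0.23 and 0.45 (exact permutation p = 0.0571, 0.0286 and 0.0179; adjusted p = 0.0709, 0.042 and 0.042). The 642 had differences of -0.16, -0.24 and -0.36 (exact permutation p = 0.171, 0.0286 and 0.0179; adjusted p = 0.205, 0.042 and 0.042). In cannabis recovery arrays as labelled, the cannabis sets passed at the highest dose alone. The 850 differed by 0.04, 0.06 and 0.57 (exact permutation p = 0.629, 0.743 and 0.0286; adjusted p = 0.676, 0.775 and 0.042). The 642 differed by -0.03, -0.06 and -0.50 (exact permutation p = 0.8, 0.8 and 0.0286; adjusted p = 0.8, 0.8 and 0.042).

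In the same cannabis recovery arrays, the probes that rose with tobacco differed from controls by 0.05, 0.09 and 0.48 (exact permutation p = 0.6, 0.486 and 0.0286; adjusted p = 0.655, 0.564 and 0.042). Those that fell with tobacco differed by -0.04, -0.10 and -0.44, none of which passed (exact permutation p = 0.8, 0.571 and 0.0571; adjusted p = 0.8, 0.632 and 0.0709).

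**Figure D3:**
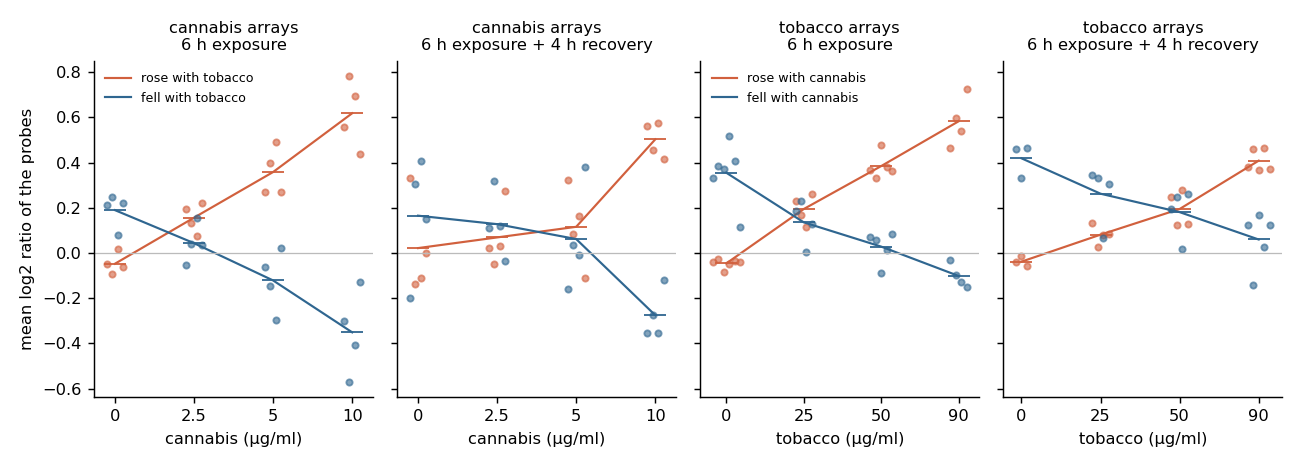
Mean log2 ratio of sets of probes called at the highest dose of one condensate at 6 h (orange rose, blue fell), shown in the arrays of the other condensate, by concentration in µg/ml. Points are arrays, dashes joined by lines are group means; at 6 h the group means of the sets moved apart with each dose. In cannabis recovery at 10 µg/ml the set that rose differed from controls by 0.48 (adjusted exact permutation p = 0.042) and the set that fell by -0.44, which did not pass (0.0709).

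At 6 h limma called 72 probes whose change differed between the condensates, 49 with the larger change in cannabis and 23 with the larger change in tobacco. The count was also reached in 5 of 100 sets of random labels, the real labels included, so it does not stand clear of chance. Of the 72, 23 were called with tobacco alone, 37 with cannabis alone and 12 with both, and the changes of 40 had opposite signs. A_51_P432641 was the clearest of the followed probes: it differed by -3.76 ± 0.68 (SE) between tobacco and cannabis (limma, Benjamini-Hochberg adjusted p = 0.00185). The probe was picked for its rise in these same cannabis arrays, which favours a large difference at 6 h. Its change with 90 µg/ml of tobacco was 0.70 (limma adjusted p = 0.167), and with 25 µg/ml after recovery it fell by 1.43 (limma adjusted p = 0.0368), a call lost without any of arrays 6, 15, 19, 20, 26 and 29 (adjusted p = 0.162, 0.107, 0.0875, 0.0827, 0.0882 and 0.123). It was also lost with quantile normalisation (0.0583), without moderation of the spread (0.0576), with only the groups compared (0.052) and with pooled controls (0.153). After recovery 18 probes differed between condensates, 14 with the larger change in tobacco, and 6 of them were among the 72, each with the same sign, where 0.0315 would be shared by independent lists. The lists are not independent, since both come from the joint fit, which gives each probe the same spread at both times. The difference of A_51_P432641 after recovery was -2.54 (limma adjusted p = 0.289), and the other followed probes did not pass at either time.

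The unadjusted p was under 0.05 for 2066 probes at 6 h and 2278 after recovery, by limma, about the numbers that chance gives over 41174 probes. The 6 h count was 46 without control 49, and the recovery count was 10 and 8 without tobacco controls 6 and 29, 6 without cannabis control 43, and 9 and 8 without cannabis arrays 41 and 66. When only the groups compared were fitted the counts were 21 and 1, and with runs of sample numbers as a block the recovery count was 37.

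**Figure D4:**
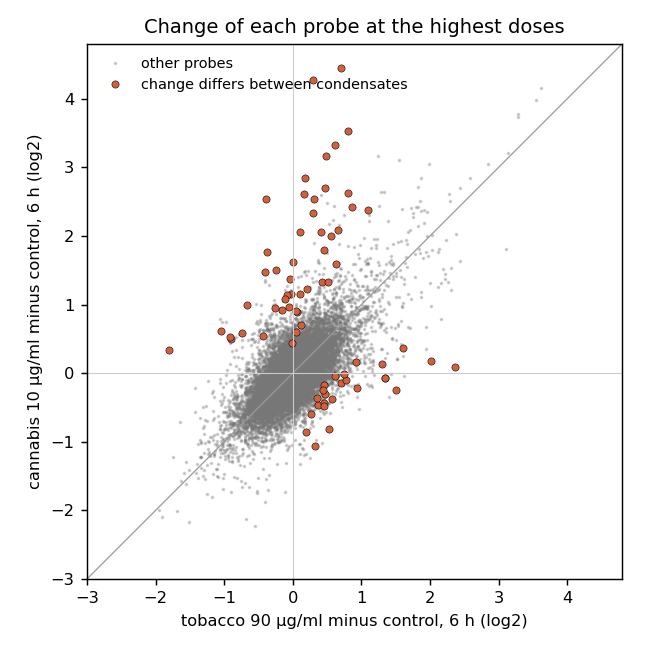
Change of each of 41174 probes at 90 µg/ml tobacco (horizontal) and 10 µg/ml cannabis (vertical) against the controls of each after 6 h, in log2 units, without the shared control on the cannabis side; the line marks equal changes. The 72 probes whose change differed between the condensates (orange) lie on both sides of the line. Over all probes, these included, the changes correlated with r = 0.65 (Spearman 0.46).

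The control arrays were also compared with each other. Between tobacco and cannabis controls limma called 0 probes at 6 h (688 at an unadjusted p under 0.05) and 0 after recovery (1522), and 0 at both times without moderation of the spread. The 688 and 1522 are fewer than chance gives at 0.05 over 41174 probes. Without tobacco control 29 the count after recovery was 1. The controls themselves differed between harvests. Recovery controls had 13 probes higher and 4 lower than 6 h controls in tobacco, and 78 higher and 65 lower in cannabis, where they include array 43. When only the groups compared were fitted both counts were 0. The tobacco count was 10 with quantile normalisation, 1 without moderation, 193 with array weights and 0 with runs of sample numbers as a block. The cannabis count was 78 without moderation, 59 without the lowest 25% of probes and 244 without arrays 43, 46 and 64. The tobacco count was 0 without any of 6 arrays (3, 9, 19, 29, 32 and 35) and was 10 without array 13 and 214 without array 23. The cannabis count was 28, 37, 60 and 347 without 6 h controls 59, 49, 37 and 40, 69 without array 35, and 62 and 33 without recovery controls 60 and 67.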

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

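The tests of exchanged labels, of a faded response and of a common response of different size were chosen only after the result was seen. That of an array-wide shift used arrays named from the data. The counts of other splits were planned for the planned comparisons, and those for highest against lowest dose and for controls came with comparisons added later.

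Over the 34 probes that part exposed from control tobacco arrays, cannabis recovery array 43, labelled control, had 88.2% on the exposed side and array 64, labelled 5 µg/ml, had 0%. Fading is argued against for array 43 alone, since it moves no control to the exposed side, and it stays open for array 64 and its 0%, as for array 46 at 8.82%. An array-wide shift of that size is argued against by random sets of matched probes, of which 0% in 1000 deviated as far in either array (1.00 and -0.91, against -0.40 to 0.26 and -0.18 to 0.45). The arrays were picked by these same 34 probes, which favours that outcome, so a smaller shift of the whole array stays open. An exchange of the labels of a control and an exposed array stays open: the presence of 1 exposed array no higher than the 6 h controls, array 64, restates the pattern and tests nothing. Splits that exchange 43 with 64 called 1683 probes against 0 as labelled, and with array 66 at 10 µg/ml 1125 against 1115, which does not tell an exchange from a mixture of RNA or uneven exposure, both untested.

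Arrays of one group differed along a shared axis that held 31.9% of the within-group variance. After each array was scaled to one SD, the first axis, computed anew, held 101% of that share. Whether it was the same axis was not checked. Arrays with a wider spread of ratios therefore stay open as the source of the shared axis. An order of processing may be behind it: neighbouring sample numbers fell on the same side in 39 of 65 pairs against a median of 32 in random orders (permutation p = 0.0586). That p keeps it open, since the labels give no processing date, and no biological explanation was tested. With runs of 8 consecutive numbers as a block the cannabis counts at 6 h were 14, 617 and 2853, against 6, 317 and 1707.

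The 72 probes that differed between condensates at 6 h were set against a single response of different size, which would put the larger change in the same condensate for nearly all of them. Of the 72, 23 had the larger change in tobacco and 49 in cannabis, which decides nothing, since calls made by chance could fall on both sides as well. Chance is not excluded: 5 of 100 reassignments of the condensate label gave at least 72, with 433 the highest of the others. A response specific to each smoke and the difference in mass dose both stay open, untested.

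Tests of the difference also gave 19 probes between times in tobacco, 15 between times in cannabis and 18 between condensates after recovery. For A_51_P432641 they gave a difference between condensates of -3.76 at 6 h. That probe was picked for its rise with cannabis at 6 h, which favours such a difference. At 6 h, 9 of the 15 cannabis probes were also among those with the larger change in cannabis than in tobacco, though these tests share arrays.

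Single arrays stood apart from their group in 6 of 165 groups of values tested, where chance gives 8.25 (about 1 in 20). A_51_P514961 was -1.92 in array 46 at 2.5 µg/ml cannabis after recovery, against 0.87 to 1.10 in the others, and -2.54 in array 64 at 5 µg/ml, against 1.42 to 1.60. A_51_P432641 was 1.44 in array 46, against -0.26 to 0.01. A_51_P514961 was 2.03 in array 18 at 50 µg/ml tobacco at 6 h, against 0.87 to 1.2. The mean of the probes that fell 6 h after the highest cannabis dose was 0.065 in array 20 at 25 µg/ml tobacco after recovery, against 0.305 to 0.346. The mean of those that rose was -0.082 in 6 h tobacco control 13, against -0.048 to -0.028.

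Other splits of the same arrays into groups of the same sizes were fitted for each count, at most 100 per comparison. Only the labelled split, of those fitted, reached the tobacco counts: 63, 740 and 1881 at 6 h (highest other 26, 18 and 1198 of 100 splits each) and 148, 489 and 2084 after recovery (17, 187 and 779 of 35, 35 and 56). The same held for cannabis at 6 h, 6, 317 and 1707 (1, 10 and 323 of 100 each), and for highest against lowest dose, 558, 535, 572 and 584 (148, 193, 2 and 105). Chance is thereby unlikely as their source but not excluded, since few splits were fitted and no adjustment was made over comparisons. The 584, for cannabis recovery, was 0 when only the groups compared were fitted. Chance was not made unlikely for 10 µg/ml cannabis after recovery, where 2 of 35 splits reached 1115 (highest other 1125). At 2.5 and 5 µg/ml the labelled count was 0, which all 35 of 35 splits reach by construction, so the splits decide nothing there (highest 26 and 1683). For differences between times, 2 of 100 reassignments reached 19 in tobacco (highest other 413) and 6 of 100 reached 15 in cannabis (665). For condensates after recovery 2 of 100 reached 18 (31). Chance was thus not made unlikely for the difference between times in cannabis. Recovery against 6 h controls gave 17 in tobacco, reached by 3 of 84 splits (highest other 125), and 143 in cannabis, reached by 4 of 100 (301). For tobacco against cannabis controls the count was 0 at both times, which all 100 and 35 splits reach by construction, so nothing is decided there either (highest 1 and 2). For differences between times and between condensates at 6 h, and for tobacco controls, the highest other splits of 413, 665, 433 and 125 were several times the labelled counts, and the cause of these was not tested. A reassignment of time or condensate labels also mixes arrays that differ by those labels, which alone can raise its count.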

How the results depend on the processing

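The alternatives that leave out arrays 43, 46 and 64 or take runs of 8 consecutive sample numbers as a block were chosen only after the data were seen; all others were planned. No single probe or set that had passed the threshold reversed its direction under any alternative. Counts were not scored for direction, and their balance of rises and falls turned over in some cases after tobacco recovery. With pooled controls, 208 rises and 281 falls at 50 µg/ml became 201 and 148. At 90 µg/ml, 985 and 1099 became 1332 and 1226. With array weights, 75 and 73 at 25 µg/ml became 234 and 359. Centring arrays on their medians kept every count within 1.5 times. Moving the shared control was tried only for the difference between condensates at 6 h and kept that count within 1.5 times. The correlations between condensates moved by less than their SE under every alternative run on them. That SE, from leaving out each array in turn (jackknife), was 0.143 at 6 h and 0.0961 after recovery. Under the alternatives other than leaving out single arrays, 683 values of single probes stayed on their side of the threshold. Another 22 passed it and 19 lost it. With each array left out in turn, 3 values of single probes passed it and 40 lost it. For sets no p was recomputed, so none could pass or lose the threshold. Each set difference moved by less than the SD pooled over its exposed and control arrays. Not run were the alternatives on gene lists and on probes per gene, which need gene names, and the restriction to complete probes, which removes none. Without intensities, no limit from signal over background can be given.

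Fitting only the groups compared gave 10 and 1010 probes at 25 and 90 µg/ml tobacco at 6 h, 37, 185 and 798 after recovery, 18, 211 and 1060 for cannabis at 6 h and 2 at 10 µg/ml after recovery. It gave 1 and 0 for differences between times, 21 and 1 between condensates, and 33, 151, 180 and 0 for highest against lowest dose in tobacco and cannabis, each at 6 h then recovery. Such fits have fewer degrees of freedom and use only the spread of their own groups. At the highest dose after recovery, 5 and 3 tobacco arrays gave 798 against 2084, and 4 and 4 cannabis arrays gave 2 against 1115. Degrees of freedom alone do not account for that contrast, and the part played by the spread was not tested. Leaving out the 25% of probes with the lowest mean tests fewer probes. The mean is that of the log ratio to the reference, so this is no filter on brightness. It gave 478 and 1224 at 50 and 90 µg/ml tobacco at 6 h and 1375 at 90 after recovery. Of the 478 and 1224, 338 and 796 rose and 140 and 428 fell. The share that rose was thus 70.7% and 65%, against 60% and 57.1% with all probes. The same filter gave 6 and 6 between times and 29 and 4 between condensates. For highest against lowest dose it gave 342 and 358 (tobacco recovery, cannabis 6 h). Array weights gave 1410 at 50 µg/ml tobacco at 6 h, 593 and 1397 at 25 and 50 after recovery, 11 and 682 at 2.5 and 5 µg/ml cannabis at 6 h, 2012 at 10 after recovery, 32 between tobacco times, 113 between condensates at 6 h, and 1419 and 2504 for highest against lowest dose after recovery. Pooled controls gave 1131 at 50 µg/ml tobacco at 6 h, 39, 684 and 3624 for cannabis at 6 h and 4365 at 10 µg/ml after recovery. A 1.5-fold change as well left 467 and 1202 at 50 and 90 µg/ml tobacco at 6 h. Quantile normalisation gave 492 at 5 µg/ml cannabis at 6 h, and no moderation gave 353 for highest against lowest cannabis dose after recovery. Without arrays 43, 46 and 64 the counts after cannabis recovery were 103 and 3388 at 5 and 10 µg/ml and 34 between times. Runs as a block gave 14, 617 and 2853 for cannabis at 6 h, 29 between tobacco times and 37 between condensates after recovery. Where construction does not show it, the cause was not tested.

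Leaving out each array in turn gave 34 to 66, 453 to 692 and 1260 to 2204 probes for tobacco at 6 h, 41 to 116, 198 to 444 and 1096 to 2287 after recovery, 3 to 7, 82 to 254 and 1105 to 1907 for cannabis at 6 h, and 0, 0 and 112 to 3011 after recovery. Differences between times ran from 6 to 33 and 11 to 29, between condensates from 46 to 83 and 6 to 26. Highest against lowest dose ran from 253 to 792 and 274 to 572 in tobacco and from 236 to 807 and 16 to 1246 in cannabis. The correlation between condensates ran from 0.54 to 0.69 at 6 h and from 0.61 to 0.70 after recovery.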

Other observations

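The sets of probes called after recovery were followed back into the arrays of the 6 h harvest and of the other condensate, tests chosen after the data were seen. Values are differences from controls by rising dose, with p from exact two-sided permutation tests adjusted over 72 tests. The 985 probes that rose after recovery from 90 µg/ml tobacco were higher by 0.24, 0.46 and 0.61 in tobacco arrays at 6 h (adjusted exact p = 0.0228 each), and the 1099 that fell differed by -0.23, -0.37 and -0.41 (adjusted exact p = 0.042, 0.0228 and 0.0228). In cannabis arrays at 6 h these sets differed by 0.16, 0.30 and 0.53 and by -0.12, -0.21 and -0.40, where the lowest dose did not pass in either set (adjusted exact p = 0.0709, 0.042 and 0.042 in both). In cannabis recovery arrays the set that rose differed by 0.09, 0.13 and 0.56, of which the last passed (adjusted exact p = 0.632, 0.564 and 0.042). The set that fell differed by -0.06, -0.11 and -0.51, and none passed (adjusted exact p = 0.726, 0.632 and 0.0709).

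The 682 probes that rose after recovery from 10 µg/ml cannabis, without the shared control in the fit, were higher by 0.22, 0.39 and 0.46 in tobacco arrays at 6 h (adjusted exact permutation p = 0.042, 0.0228 and 0.0228). After tobacco recovery they differed by 0.19, 0.35 and 0.55, of which the first did not pass (adjusted exact p = 0.0709, 0.042 and 0.042). In cannabis arrays at 6 h they were higher by 0.17, 0.40 and 0.70 (adjusted exact p = 0.042 each). The 454 that fell differed by -0.26, -0.39 and -0.41 in tobacco arrays at 6 h (adjusted exact p = 0.0228 each) and by -0.32, -0.47 and -0.62 after tobacco recovery (0.042 each). In cannabis arrays at 6 h they differed by -0.11, -0.28 and -0.64, of which the first did not pass (adjusted exact p = 0.105, 0.042 and 0.042).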
